A study of Mus musculus with 6 samples.

How the data were processed

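Total RNA of mouse embryonic fibroblasts, fibroblast cultures grown from embryos, was measured on 6 single-colour Affymetrix arrays. Per the labels' protocols, cells were kept in 10% foetal bovine serum, infected with retroviruses for Oct4, Sox2 and Klf4 on day 0 and sampled on day 8. RNA was extracted with a column kit that included a DNase step, and 300 ng was copied into a biotin-labelled target by the Affymetrix whole transcript method, per the labels' protocols. Each array was assigned to a genotype (Foxd1+/+, Foxd1+/- or Foxd1-/-) by its title, with 2 arrays per genotype called biological replicates. The labels do not say whether the replicates came from separate embryos, so p-values measure the spread between these arrays.

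The authors deposited 1 table of intensity values on a linear scale for 28856 probe sets. The background correction, normalization and summary method behind the deposited intensity values are not given in the sources used here. Median intensity per array lay between 76.5 and 79.6 and the lowest value was 19.5, so the values look scaled between arrays, but the method stays unknown. No columns of 2 arrays were identical. No detection call accompanies the values used here, and the signal over background of a dim gene is therefore unknown.

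Probe sets were named through the platform annotation supplied with the table. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 5446 had none listed. Symbols were looked up by Entrez identifier in a RefSeq gene table (assembly GRCm38.p6, used only for names and neighbours), where 21698 matched and 0 names changed. Only probe sets with 1 symbol were used. For the 999 genes with several probe sets the one with the highest mean was kept, which left 19938 genes. No coordinates are given, because the files name no genome build.

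Values were tested as log2(intensity + 1), which understates differences of dim genes. The main fit was limma (version 3.58.1 in R 4.3.3) with lmFit and eBayes on all 6 arrays, 1 mean per genotype and no block, which leaves 3 residual degrees of freedom. Benjamini-Hochberg adjustment was used with a threshold of 0.05 over all genes of a comparison. The comparisons were the 3 pairs of genotypes, Foxd1+/- against the midpoint of the other 2 genotypes, and any difference over the 3 genotypes. Figures were drawn with matplotlib 3.10.9.

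Gene lists for this cell type and treatment were fixed before the data were examined. They covered the pluripotency network, reprogramming intermediate markers, epithelial junctions and keratins, mesenchymal and fibroblast identity, contractile and smooth muscle genes, TGF-beta response, BMP and Wnt pathways, cell cycle, p53 targets and senescence, inflammatory and secretory genes, interferon response, mesendoderm and germ layers, neural crest and neurons, skeletal muscle, cartilage and bone, adipocytes, macrophages and leukocytes, endothelium, erythroid cells, kidney stroma and nephron progenitors, forkhead genes, posterior and anterior Hox genes, glycolysis, oxidative phosphorylation, endoplasmic reticulum stress, and cholesterol synthesis. These 27 lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with limma's fry. None of the lists was called with an estimated correlation or with fry's directional test in any comparison. fry's mixed test, which ignores direction, called 0 lists in the 3 genotype pairs without the replicate block. With the block it called the mesenchymal list in Foxd1-/- against Foxd1+/+ (limma adjusted p = 2.97e-06) and against Foxd1+/- (1.46e-04), and the posterior Hox list in the former (0.027). For Foxd1-/- against the other 4 arrays it called 3 lists without the block and 11 with it. A further list of sex chromosome markers was read per array and not tested.

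The genes named in the text follow a rule fixed before the data were examined. It takes Foxd1, Pou5f1, Sox2 and Klf4. For each pair of genotypes it takes up to 8 genes higher and 8 lower whose arrays do not overlap, by the size of the change among those that passed, and otherwise by p among those with a log2 difference of at least 1, leaving out provisional names and large receptor families. It adds up to 4 members with the smallest p from each list. Genes from the second part did not pass the test, as no gene did.

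The genotypes share the replicate numbers 1 and 2, and the labels do not say what a number marks. Differences between replicate 1 and replicate 2 correlated across genes between genotypes, with r of 0.55 for Foxd1+/+ and Foxd1+/-, 0.73 for Foxd1+/+ and Foxd1-/-, and 0.73 for Foxd1+/- and Foxd1-/-. By the rule fixed for this check the numbers were treated as pairing the arrays, on the evidence of the data alone. With only 2 numbers this evidence is weak, since the numbers of the 3 genotypes can be matched in 4 ways and chance would give agreement of all 3 in 1 of 4. The main fit nevertheless held no block, so each SE and p-value given without mention of the block leaves this pairing out. The fit with the number as a block leaves 2 residual degrees of freedom, and its value is given where it changed a call.

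The fits were tested on simulated data for the 19938 genes of the Foxd1-/- against Foxd1+/+ comparison. Without the block they recovered 59.7% of genes changed by 1 on the log2 scale, 85.1% changed by 2 and 94.0% changed by 3. With the block the shares were 65.7%, 89.6% and 98.5%. The changed genes had a mean above 6 on the log2 scale, and noise was drawn independently for each array. Only the draws with the block held a deviation shared by arrays of the same number, so these shares need not hold here. Without the block, Foxd1, with a log2 difference of -2.89, had an adjusted p of 0.99985 in limma.

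Alternatives were quantile normalization, median centring, filters on the lowest 25% and the lowest 50% of genes by mean, an intensity trend and a robust prior in eBayes, only the genotypes compared, the replicate block, all probe sets, the mean over probe sets, an offset of 16, each array left out in turn, genes within 20 Mb of Foxd1 left out (170 genes), X and Y genes left out (748 genes), and other thresholds. Chosen after seeing the data were the fits without the arrays numbered 2 of Foxd1+/+ and Foxd1+/-, with 16 subtracted before the log, with a term for the 2 arrays low in Xist, with an estimated correlation under the other alternatives, and of Foxd1-/- against the other 4 arrays.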

Results

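Expression was measured in mouse embryonic fibroblasts of 3 Foxd1 genotypes during reprogramming, the conversion of a differentiated cell towards pluripotency by added transcription factors. The cells carried retroviruses for 3 factors, Oct4 (gene symbol Pou5f1), Sox2 and Klf4, and were taken on day 8 after infection. Each genotype, Foxd1+/+, Foxd1+/- and Foxd1-/-, had 2 arrays labelled as biological replicates 1 and 2, so that 6 arrays held 28856 probe sets each. Median intensity per array lay between 76.5 and 79.6, and the lowest intensity on any array was 19.5. With 2 arrays per genotype, an exact rank test of 2 against 2 cannot give a p below 0.333. The comparisons ask what loss of 1 or both copies of Foxd1, a forkhead transcription factor of the embryonic kidney stroma and retina, does to the expression of cells under reprogramming.

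Foxd1 itself (probe set 10406845) read low on both arrays labelled Foxd1-/-, at intensities of 189 and 213. The arrays labelled Foxd1+/+ gave 1907 and 1169, and those labelled Foxd1+/- gave 1014 and 2074. The means were 1538 ± 522 (SD, n = 2) for Foxd1+/+, 1544 ± 749.5 (SD, n = 2) for Foxd1+/- and 201 ± 17.0 (SD, n = 2) for Foxd1-/-. Foxd1 was therefore 7.41-fold lower in Foxd1-/- than in Foxd1+/+ on the log2 scale of the fit, with no overlap between arrays. The part of the gene that was deleted, and whether the probe set lies inside it, is not given in the sources used here. The order of Foxd1+/+ and Foxd1+/- went one way in replicate 1 and the other way in replicate 2, where the array labelled Foxd1+/- held more Foxd1 than the array labelled Foxd1+/+. The Foxd1 level thus goes against the labels of these arrays, and the direction of each comparison below is that of the arrays as labelled.

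Of the delivered factors, Pou5f1 read 580 and 138 in the arrays labelled Foxd1+/+, 331 and 298 in Foxd1+/-, and 348 and 145 in Foxd1-/-. Its log2 difference between Foxd1-/- and Foxd1+/+ was -0.33 ± 0.79 (SE), smaller than the spread between replicates, and it turned to 0.70 without Foxd1+/+ replicate 1 and 0.30 without Foxd1-/- replicate 2. Sox2 differed by -0.26 ± 0.31 and Klf4 by 0.10 ± 0.08 (SE, n = 2 arrays each) in the same comparison, and neither passed. The Sox2 difference turned to 0.0079 and 0.0012 without the same arrays. Whether these probe sets read the retroviral transcript, the cell's own transcript or both is not given in the sources used here.

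**Figure D1:**
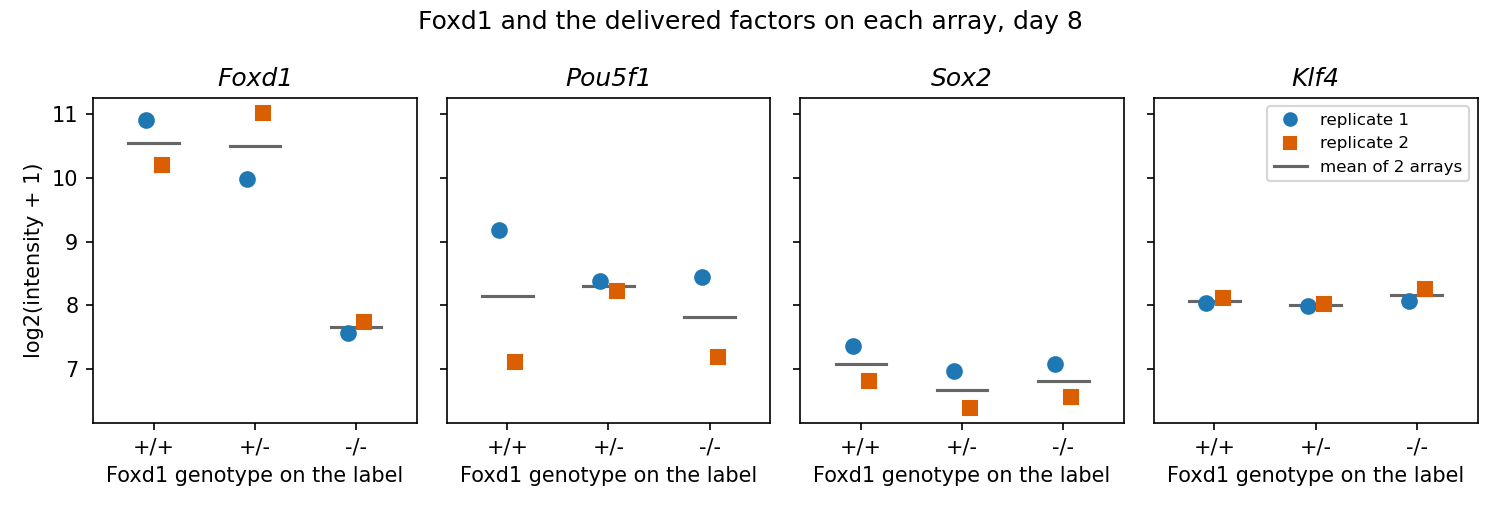
Log2(intensity + 1) of Foxd1, Pou5f1, Sox2 and Klf4 on each of the 6 arrays by the genotype on the label, with circles for replicate 1, squares for replicate 2 and a line for the mean of 2 arrays. Foxd1 lies at 7.57 and 7.74 on the Foxd1-/- arrays and between 9.99 and 11.02 on the other 4.

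Between the arrays labelled Foxd1-/- and Foxd1+/+, which ask for the effect of losing both copies, the genes lower in Foxd1-/- by at least 1 on the log2 scale with no overlap between arrays were Foxd1, the orphan receptor Nr0b1 of the pluripotency network, and the axon guidance cue Sema3e. Their log2 differences were -2.89 ± 0.41, -1.64 ± 0.55 and -1.22 ± 0.31 (SE, n = 2 per genotype). Higher in Foxd1-/-, with no overlap between arrays, were the interferon response regulators Irf7 (1.28 ± 0.87) and Dhx58 (1.05 ± 0.71), the interferon-induced Trim30a (1.27 ± 0.85), and Xist, the RNA that coats the inactive X chromosome (2.42 ± 1.88). These differences depended on single arrays: with 1 array left out they ranged from 0.52 to 2.03 for Irf7, 0.37 to 1.73 for Dhx58, 0.51 to 2.04 for Trim30a, 0.50 to 4.33 for Xist and -2.31 to -0.98 for Nr0b1. Leaving out 1 array, above and below, leaves the replicate numbers unequal between genotypes, so such values mix genotype with replicate number. Xist intensity was 514 and 35 on the Foxd1+/+ arrays, and 623 and 848 on the Foxd1-/- arrays. Sex markers thus differed between these groups along with genotype. Lack of overlap alone says little: 5127 of the 19938 genes (25.7%) did not overlap in this comparison, where chance gives 33.3%. None of the 19938 genes passed: limma called 0 genes, the smallest adjusted p was 0.99985, and Foxd1 had an unadjusted p of 0.00111. At an unadjusted p under 0.05 there were 421 genes, 222 higher and 199 lower, where chance gives 997. With the replicate number as a block, limma also called 0 genes, the smallest adjusted p was 0.489 and the unadjusted count was 1503. The chance figures here and below hold for independent arrays. These arrays deviated together by replicate number, so a count below such a figure does not show a genotype effect weaker than chance. The count of 421 moved to 818 without Foxd1-/- replicate 1 and 199 without Foxd1-/- replicate 2.

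Among the gene lists, the cell cycle list was lower in Foxd1-/- in all 40 measured members, with a median log2 difference of -0.24. Rrm1, a subunit of the enzyme that makes deoxynucleotides, differed by -0.37 ± 0.11, topoisomerase Top2a by -0.30 ± 0.16 and the spindle checkpoint kinase Bub1b by -0.40 ± 0.24 (SE, n = 2 per genotype). limma's camera with a preset correlation called this list (adjusted p = 4.4e-08), and the call was lost at an adjusted p = 0.70 with an estimated correlation in limma. Without Foxd1+/+ replicate 1 the limma adjusted p was 0.27, and without Foxd1-/- replicate 2 the direction turned (0.46).

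Interferon response genes went the other way, with all 33 measured members higher in Foxd1-/- and a median log2 difference of 0.84. The antiviral sensors Oas1a and Oas2 differed by 0.60 ± 0.23 and 0.91 ± 0.45, and the interferon-induced Xaf1 by 0.67 ± 0.31 (SE, n = 2 per genotype). camera in limma gave an adjusted p = 6.4e-08, and an adjusted p = 0.70 with an estimated correlation. Adjusted over the list alone, 0 members passed without the replicate block and 26 with it, while over all genes 0 passed in either fit. Replicate number moved this list more than genotype did: its mean, relative to the 6 arrays, was -0.82 and 0.18 in Foxd1+/+, -1.04 and 0.64 in Foxd1+/-, and -0.23 and 1.27 in Foxd1-/-. The limma adjusted p was 0.10 without Foxd1+/+ replicate 1 and 0.47 without Foxd1-/- replicate 2.

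Mesenchymal and fibroblast genes were higher in 35 of 41 members (median 0.19), among them the growth factor receptor Pdgfra (0.71 ± 0.17), the homeobox gene Meox2 (0.29 ± 0.07), the transcription factor Osr1 (0.33 ± 0.15) and the collagen gene Col1a2 (0.23 ± 0.10; SE, n = 2 per genotype). camera in limma gave an adjusted p = 4.8e-05, and an adjusted p = 0.70 with an estimated correlation. Over the list alone 14 members passed with the replicate block and 0 without it. Without Foxd1+/+ replicate 1 the limma direction turned (adjusted p = 0.51), and without Foxd1-/- replicate 2 the value was 0.46.

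Markers of macrophages and other leukocytes, a cell type that embryo fibroblast cultures can hold, were lower in Foxd1-/- in 22 of 26 members (median -0.19). Lysozyme genes Lyz2 and Lyz1 differed by -0.66 ± 0.12 and -0.39 ± 0.07, the growth factor receptor Csf1r by -0.16 ± 0.07 and the lectin Clec4d by -0.33 ± 0.14 (SE, n = 2 per genotype). camera in limma gave an adjusted p = 7.7e-08, and an adjusted p = 0.49 with an estimated correlation. This call held without each array in turn. Over the list alone 3 members passed with the replicate block and 0 without it.

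Posterior Hox and limb genes were higher in 15 of 21 members by a median of 0.07, with Isl1 at 0.24 ± 0.06, Hoxd12 at 0.36 ± 0.11 and Hoxc9 at 0.38 ± 0.14 (SE, n = 2 per genotype). The limma camera call was narrow (adjusted p = 0.047, and adjusted p = 0.70 with an estimated correlation). It ended without genes near Foxd1 (0.099 by limma), without Foxd1+/+ replicate 1 (0.29) and without Foxd1-/- replicate 2 (0.46).

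The pluripotency list, which holds the genes that reprogramming switches on, was lower in 28 of 37 members with a median of -0.06 and did not pass in limma (adjusted p = 0.080). With the replicate block it did (limma adjusted p = 0.014, and adjusted p = 0.76 with an estimated correlation). Nr0b1 led the list, followed by L1td1 (-0.34 ± 0.12), the growth factor Fgf4 (-0.47 ± 0.21) and the homeobox gene Nanog (-0.48 ± 0.24; SE, n = 2 per genotype), each lower on both Foxd1-/- arrays than on both Foxd1+/+ arrays. Such a separation, in either direction, held for 25.7% of all genes, where chance gives 33.3% for independent arrays. The fits that follow with an array left out hold unequal replicate numbers. This list read higher in replicate 1 than in replicate 2 of each genotype. The list passed without Foxd1+/+ replicate 2 (limma adjusted p = 8.1e-11, and adjusted p = 0.63 with an estimated correlation) and without Foxd1-/- replicate 1 (9.5e-05, and adjusted p = 0.73 with an estimated correlation). The direction turned without Foxd1+/+ replicate 1 (0.0023, and adjusted p = 0.96 with an estimated correlation) and without Foxd1-/- replicate 2 (0.46). Without the arrays numbered 2 of Foxd1+/+ and Foxd1+/-, chosen after seeing the Foxd1 levels, limma's adjusted p was 2.6e-10 (adjusted p = 0.76 with an estimated correlation), and limma still called 0 single genes in this comparison. Epithelial junction and keratin genes, which reprogramming cells gain as they lose fibroblast character, were lower in 22 of 36 members (median -0.02) and did not pass (limma adjusted p = 0.38). Krt18, a simple epithelial keratin, differed by 0.28 ± 0.10 and the epithelial regulator Grhl2 by -0.35 ± 0.13. Without Foxd1+/+ replicate 2 the epithelial list passed (4.8e-04 by limma, and adjusted p = 0.63 with an estimated correlation), and its direction turned without Foxd1+/+ replicate 1 (0.16) and without Foxd1-/- replicate 2 (0.47).

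Genes of the BMP and Wnt pathways, among them the Wnt feedback gene Axin2 (0.34 ± 0.09), had a median of 0.12 with 18 of 24 members higher (limma adjusted p = 0.080, and 0.0035 with the replicate block). The latter was an adjusted p = 0.57 with an estimated correlation in limma. No other list passed. Median log2 differences were 0.06 for the inflammatory and cholesterol synthesis lists (0.058 and 0.064), 0.05 for TGF-beta, 0.04 for cartilage and bone, 0.01 for endothelial, kidney stroma and adipocyte genes (0.014, 0.012 and 0.007), 0.002 for skeletal muscle, and 0.001 for both the endoplasmic reticulum stress list and the forkhead family. They were -0.12 for contractile genes, -0.04 for p53 targets and for intermediate reprogramming markers, -0.03 for neural crest and for erythroid genes, -0.01 for mesendoderm, glycolysis, oxidative phosphorylation and anterior Hox genes (-0.007, -0.008, -0.007 and -0.013). In 6 of the 27 lists the mean had the opposite sign to the median.

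**Figure D2:**
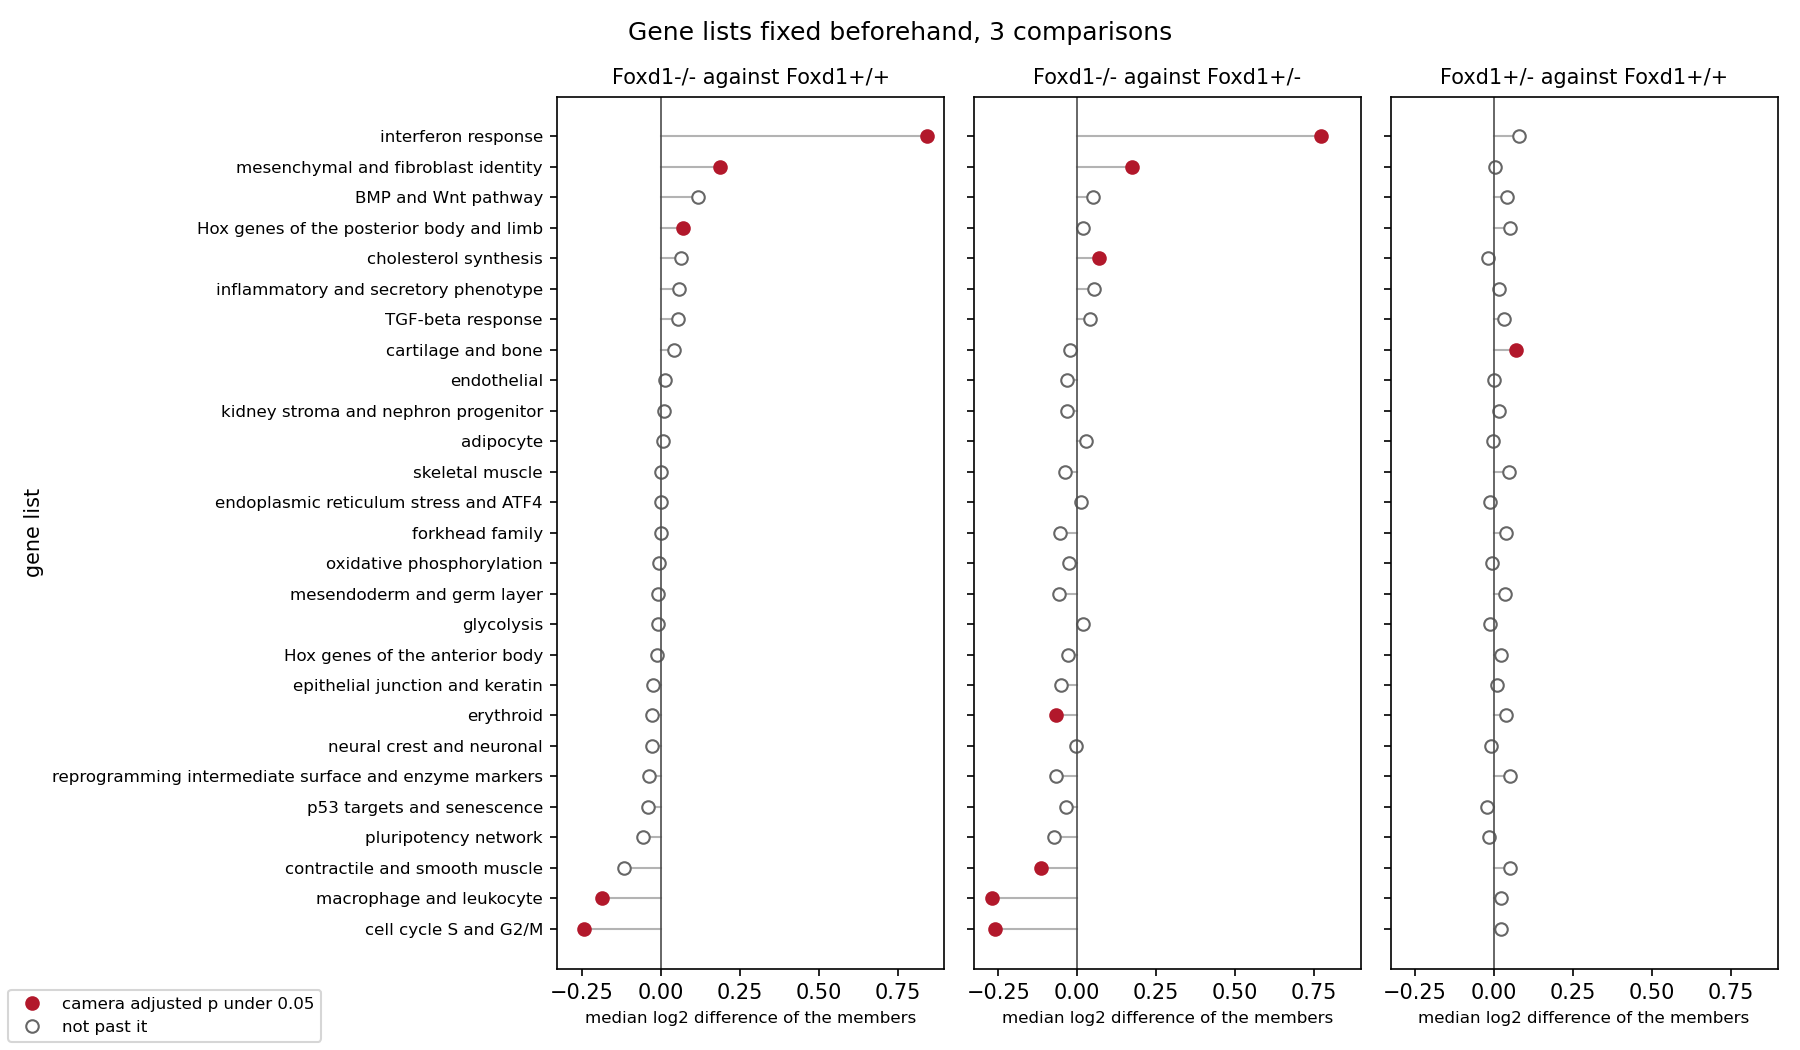
Median log2 difference of the members of 27 gene lists in 3 comparisons, with filled points for lists that limma's camera called at an adjusted p under 0.05 with a preset correlation. In Foxd1-/- against Foxd1+/+ the interferon list lies at 0.84 and the cell cycle list at -0.24, and 0 lists are called with an estimated correlation.

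Between the arrays labelled Foxd1-/- and Foxd1+/-, which ask for the effect of the remaining copy, Foxd1 (-2.85 ± 0.41), Nr0b1 (-1.83 ± 0.55), Sema3e (-1.19 ± 0.31) and the epidermal gene Sprr2b (-1.10 ± 0.24) were lower in Foxd1-/- with no overlap between arrays (log2 difference ± SE, n = 2 per genotype). Apol6 was higher by 1.19 ± 0.56. In this comparison 25.6% of all genes did not overlap, where chance gives 33.3%. The Y-linked Kdm5d read -1.15 ± 1.09, with log2 levels of 7.07 on array 1 of Foxd1+/- and 4.84 on array 2. No gene passed: limma called 0 of 19938 genes without and with the replicate block, with 460 and 1507 genes at an unadjusted p under 0.05 where chance gives 997. With 1 array left out the 460 ranged from 169 to 925, and the log2 differences from 0.39 to 1.99 for Apol6, -2.27 to -0.036 for Kdm5d and -2.50 to -1.17 for Nr0b1.

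Of the 5 lists called in the first comparison, 4 were called here as well, on the same Foxd1-/- arrays. All 40 cell cycle genes were lower (median -0.26), with Rrm1 at -0.32 ± 0.11, Top2a at -0.27 ± 0.16 and the kinetochore gene Cenpf at -0.35 ± 0.15, and all 33 interferon genes were higher (median 0.77), with Oas1a at 0.36 ± 0.23 and Oas3 at 0.65 ± 0.47. Leukocyte markers were lower in 24 of 26 members (median -0.27), with Lyz2 at -0.67 ± 0.12, Lyz1 at -0.30 ± 0.07, Clec4d at -0.43 ± 0.14 and the signalling adaptor Tyrobp at -0.28 ± 0.08. Mesenchymal genes were higher in 30 of 41 members (median 0.17), with Pdgfra at 0.72 ± 0.17, Col1a2 at 0.22 ± 0.10 and the matrix gene Thbs2 at 0.22 ± 0.11 (SE, n = 2 per genotype). limma's camera gave adjusted p values of 3.4e-08, 5.2e-06, 3.4e-08 and 2.0e-04 for these 4 lists. Each call was lost with an estimated correlation, at an adjusted p = 0.76 for the cell cycle, interferon and mesenchymal lists and an adjusted p = 0.43 for the leukocyte list. Without Foxd1-/- replicate 2 the cell cycle and interferon directions turned (limma adjusted p = 0.89 and 0.99) and the mesenchymal list did not pass (0.68). Without Foxd1+/- replicate 1 the interferon direction turned (0.82 by limma) and the mesenchymal list did not pass (0.15).

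Contractile genes were lower in 18 of 19 members (median -0.11), among them the smooth muscle genes Tagln (-0.55 ± 0.42) and Actg2 (-0.39 ± 0.27), the intermediate filament gene Des (-0.27 ± 0.18) and tropomyosin Tpm1 (-0.27 ± 0.19; SE, n = 2 per genotype). With 1 array left out these ranged from -1.05 to -0.054 for Tagln, -0.68 to -0.093 for Actg2, -0.48 to -0.065 for Des and -0.38 to -0.16 for Tpm1. Erythroid genes were lower in all 9 members (median -0.07), with the transferrin receptor Tfrc at -0.43 ± 0.18 and the red cell membrane gene Epb42 at -0.20 ± 0.06. Cholesterol synthesis genes were higher in 15 of 18 members (median 0.07), with their regulator Srebf2 at 0.13 ± 0.07. camera in limma gave adjusted p values of 0.0046, 0.016 and 0.017, and each list had an adjusted p = 0.76 with an estimated correlation. Without Foxd1+/- replicate 1 the contractile list had a limma adjusted p of 0.84 and the erythroid list 0.11. Without Foxd1+/- replicate 2 the erythroid list had 0.059 and the direction of the cholesterol list turned (0.86 by limma). Without Foxd1-/- replicate 1 the erythroid list had 0.053, and without Foxd1-/- replicate 2 the 3 lists had 0.19, 0.19 and 0.33.

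Pluripotency genes were lower in 26 of 37 members (median -0.07; limma adjusted p = 0.23), with L1td1 at -0.32 ± 0.12 and Klf5, a factor of the same network, at 0.38 ± 0.18. The list passed with the replicate block (limma adjusted p = 0.035, and adjusted p = 0.75 with an estimated correlation). Without Foxd1-/- replicate 1 it passed too (6.2e-04 by limma, and adjusted p = 0.72 with an estimated correlation), and without Foxd1-/- replicate 2 its direction turned (0.33). BMP and Wnt genes had a median of 0.05 (limma adjusted p = 0.28, 0.040 with the block, and adjusted p = 0.58 with the block and an estimated correlation). Epithelial genes had a median of -0.05 and did not pass (limma adjusted p = 0.28), with Grhl2 at -0.40 ± 0.13 and the keratin Krt19 at 0.25 ± 0.10. Their direction turned without Foxd1-/- replicate 2 (0.95 by limma).

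Between the arrays labelled Foxd1+/- and Foxd1+/+, which ask for the effect of losing 1 copy, no gene reached a log2 difference of 1 in either direction. Foxd1 differed by -0.04 ± 0.41 (SE, n = 2 per genotype), with -0.91 in replicate 1 and 0.83 in replicate 2. Pou5f1 differed by 0.15 ± 0.79, Sox2 by -0.40 ± 0.31 and Klf4 by -0.07 ± 0.08. limma called 0 of 19938 genes without and with the replicate block, and at an unadjusted p under 0.05 there were 194 and 400 genes where chance gives 997. With 1 array left out the 194 ranged from 115 to 642. Genes among the 4 smallest unadjusted p of their lists included the adipocyte regulator Cebpb (0.21 ± 0.06), Krt19 (-0.27 ± 0.10), Meox2 (0.19 ± 0.07), the p53 target Sesn1 (-0.22 ± 0.10), the interferon-induced Oasl1 (0.44 ± 0.26) and the pluripotency marker Zfp42 (-0.13 ± 0.07).

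Cartilage and bone was the only list of 27 that camera called in this comparison, higher in Foxd1+/- in 17 of 21 members by a median of 0.07 (limma adjusted p = 0.012, and adjusted p = 0.98 with an estimated correlation). Its members with the smallest p were the matrix genes Matn1 (0.20 ± 0.07), Snorc (0.12 ± 0.06), Col9a1 (0.13 ± 0.08) and Comp (0.07 ± 0.05; SE, n = 2 per genotype). The replicate block ended this call (limma adjusted p = 0.052), as did quantile normalization (0.12), a filter on the lowest 25% of genes (0.27), and leaving out Foxd1+/+ replicate 2 (0.23) or Foxd1+/- replicate 2 (0.43). Pluripotency, mesenchymal and epithelial genes had medians of -0.02, 0.005 and 0.01 and did not pass (limma adjusted p = 0.94 each). In these 3 lists 1 array decided the direction: without Foxd1+/+ replicate 1 the pluripotency list read higher and the mesenchymal list lower in Foxd1+/- (limma adjusted p = 2.48e-06 and 1.5e-05), and without Foxd1+/+ replicate 2 they read the other way (1.1e-09 and 1.3e-08). Without Foxd1+/- replicate 2 both directions also turned (0.67 and 0.16 by limma). For the epithelial list the same omissions gave limma adjusted p values of 9.6e-04 and 0.0021, higher and lower in Foxd1+/-. With an estimated correlation each of these lists had an adjusted p = 0.95 without Foxd1+/+ replicate 1 and an adjusted p = 0.89 without Foxd1+/+ replicate 2.

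The Foxd1+/- arrays were also set against the midpoint of Foxd1+/+ and Foxd1-/-, to ask whether 1 copy gives an intermediate state. Foxd1 itself lay level with Foxd1+/+ in this group (log2 difference -0.04 ± 0.41, SE). The contrast therefore cannot tell what 1 copy does, and it holds the same Foxd1-/- arrays as the comparisons above. limma found 0 genes away from the midpoint, with 263 at an unadjusted p under 0.05 (113 to 810 with 1 array left out), or 756 with the replicate block. Leukocyte markers lay above the midpoint in 23 of 26 members (median 0.12), cell cycle genes in 39 of 40 (0.14), contractile genes in 17 of 19 (0.12), erythroid genes in 9 of 9 (0.06) and cartilage genes in 15 of 21 (0.05). Interferon genes lay below it in 32 of 33 members (-0.33) and mesenchymal genes in 30 of 41 (-0.08). camera in limma gave adjusted p values from 8.9e-05 for the leukocyte list to 0.037 for the mesenchymal list. With an estimated correlation none passed in limma, the lowest value being an adjusted p = 0.70, and the cartilage call also ended with the block (adjusted p = 0.13). A test over all 3 genotypes together called 0 genes in limma, with 272 at an unadjusted p under 0.05 (97 to 511 with 1 array left out) and 1121 with the block.

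**Figure D3:**
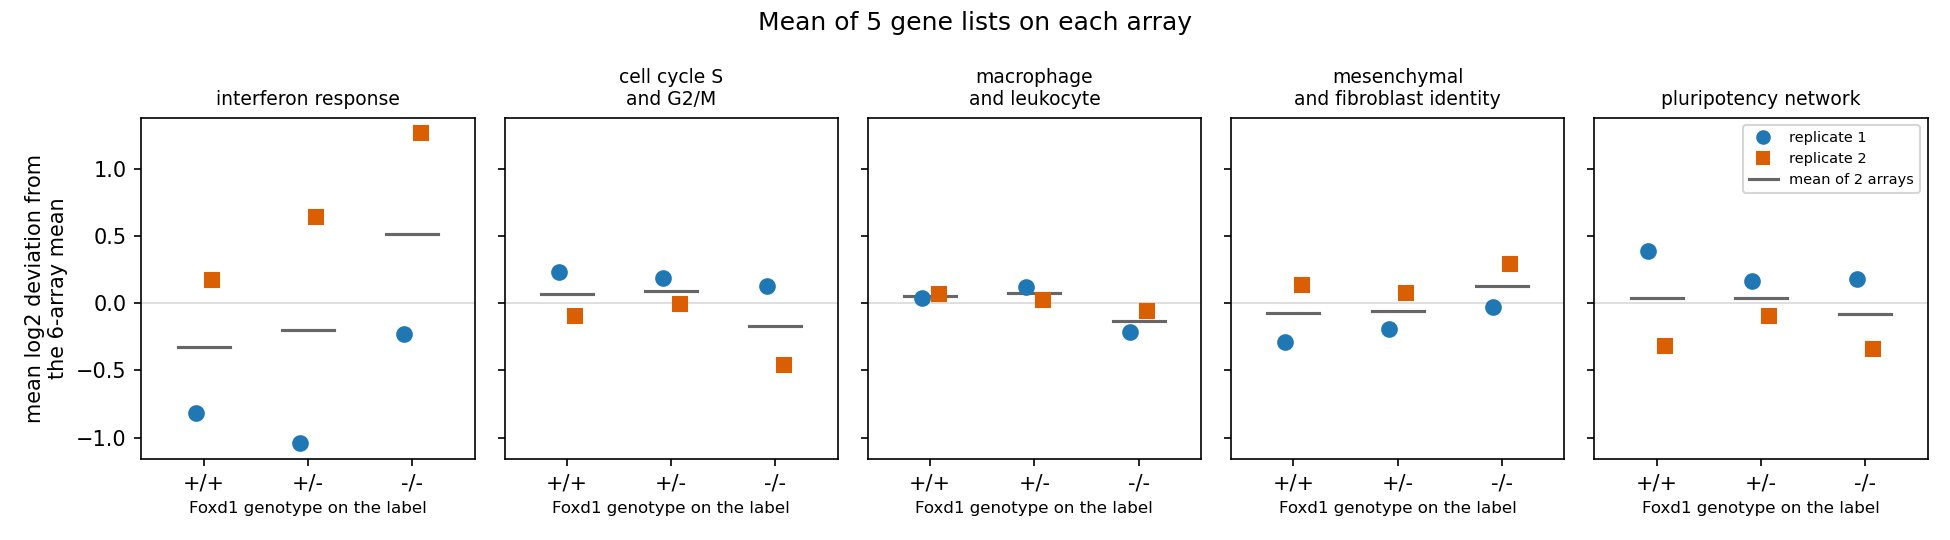
Mean log2 deviation of 5 gene lists from the mean of the 6 arrays, by the genotype on the label, with circles for replicate 1, squares for replicate 2 and a line for the mean of 2 arrays. The interferon list spans -1.04 to 1.27, and every replicate 2 array lies above the replicate 1 array of its genotype. The leukocyte list lies lowest on both Foxd1-/- arrays, at -0.21 and -0.05.

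The fold changes of Foxd1-/- and of Foxd1+/- against the shared Foxd1+/+ arrays had a Pearson r of 0.27 and a Spearman rho of 0.31 across the 19938 genes, which are not independent replicates. Unchanged groups drawn against the same controls, with the spread between replicates, gave a mean r of 0.50 (0.43 to 0.55 over 100 draws) and a mean rho of 0.45 (0.43 to 0.47). With the spread left by the replicate block r was 0.50 (0.42 to 0.61). The covariance was 0.0030, against 0.0197 and 0.0065 in these draws. The observed values lay below the drawn ranges. The draws held each array independent of the others, which does not describe these arrays. They therefore cannot tell whether the 2 fold changes share an effect. The r depended on single arrays, at 0.62 without Foxd1+/+ replicate 1, 0.74 without Foxd1+/+ replicate 2 and -0.21 without Foxd1+/- replicate 2. No draws were made with an array left out, so these values have no drawn range to stand beside.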

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

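The tests of array similarity and of leukocyte markers were chosen after their results were seen, and the remaining tests below before. For the interferon tone between cultures, the prediction did not say whether 1 or both replicate numbers had to meet it, and the reading that both must was settled after the list means had been seen.

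Genes were picked out where the difference between the arrays labelled Foxd1+/- and Foxd1+/+ went opposite ways in replicate 1 and replicate 2 by at least 0.5 on the log2 scale. The difference between the replicate numbers was not tested. Foxd1 gave -0.91 and 0.83, and Pou5f1 gave -0.81 and 1.11. Xist, expressed from the inactive X of female cells, gave -3.89 and 4.26. The Y-linked genes gave 3.29 and -3.41 for Uty, 2.37 and -2.37 for Kdm5d, and 3.14 and -3.30 for Eif2s3y. The array labelled Foxd1+/+ 2 and the array labelled Foxd1+/- 1 were thus low in Xist and high in Y-linked genes, and the other 4 arrays, both Foxd1-/- arrays included, were high in Xist. Among 11991 genes with a mean above 6 on the log2 scale, 38 moved oppositely by at least 0.5 in both numbers, 35 of them autosomal, and 0 moved the same way.

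For this opposite order of Foxd1, the first pattern weighed, a candidate explanation is that the labels of the Foxd1+/+ and Foxd1+/- arrays numbered 2 were exchanged. After centring within each replicate number, autosomal genes away from Foxd1 correlated better between crossed pairs (0.34 and 0.51) than between labelled pairs (-0.10 and -0.12), and the mean difference in r was 0.54. The sex of the cultures predicts the same pairs, since Xist and the Y-linked genes split these 4 arrays the same way. A test on 100 autosomal genes placed the Foxd1-/- arrays at 0.31 (95% bootstrap interval 0.16 to 0.39) between the Xist-high arrays at 0 and the Xist-low arrays at 1, which decides neither way. The interval resamples genes and not arrays, so it does not measure the spread between cultures. The genes were picked for separating the arrays that define 0 and 1, and 30 of the 100 lay outside that range. Near Foxd1, 0 genes differed enough in Foxd1-/- to serve as a marker of genotype. Exchanged labels and sex cannot be told apart here, because both group the same arrays, and variation between cultures of 1 genotype stays open as untested.

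The second pattern is the higher interferon response in Foxd1-/-. Leukocytes in the culture are argued against, because their markers read lower in Foxd1-/- (median -0.24 against the other 4 arrays). An offset of 16 added before the log is argued against as well, since the list median kept 0.97 of its value. Median centring and quantile normalization could not decide on scaling, because the arrays were already alike (median intensity 76.5 to 79.6). Scaling before the values were deposited therefore stays open. An interferon tone that varies from culture to culture may account for it: the arrays that are not Foxd1-/- differed from each other by 0.32 of the Foxd1-/- difference in replicate 1 and 0.54 in replicate 2, which leaves this open. In both numbers the lower of the arrays that are not Foxd1-/- was the one low in Xist. Both Foxd1-/- arrays were high in Xist, and sex or exchanged labels were not tested for this pattern. Against the Xist-high array of its number, the Foxd1-/- list mean was -0.23 against -0.82 in replicate 1 and 1.27 against 0.64 in replicate 2. An effect of the genotype stays open too, with the Foxd1-/- array 0.70 above the mean of the other arrays in replicate 1 and 0.86 above in replicate 2, and replicate 2 lying 1.39 above replicate 1.

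The third pattern is the likeness of arrays with the same replicate number, which chance would give in 1 of 4 cases for 2 numbers and 3 genotypes. Quantile normalization left the mean correlation of replicate differences at 0.67. This test could not decide on array scaling. A scale factor per array hardly alters a correlation across genes, and the arrays were already alike (median intensity 76.5 to 79.6). What the number marks, such as a shared infection or day, is not given in the sources used here and was not tested.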

How the results depend on the processing

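The fits without the arrays numbered 2 of Foxd1+/+ and Foxd1+/-, with a Xist term, with 16 subtracted, and with an estimated correlation under the other alternatives were chosen after seeing the data. No signal over background was used here, so what it limits is unknown. Counts of 0 genes hold for the labels as given, and there they stayed at 0 under every alternative but 1. With a term for low Xist, limma called 1 gene, Foxd1, for Foxd1-/- against the other 4 arrays. That term splits the arrays as Foxd1's own levels do and leaves only the 2 other Xist-high arrays as the reference, so the call was built into the choice of term. Fits with the labels of the Foxd1+/+ and Foxd1+/- arrays numbered 2 exchanged, tried while exploring, called genes in each genotype pair. They are not used here, because they group arrays by a measured level, and the 0 counts would not stand if those labels were exchanged. Of 78 named gene values, 1679 of 1689 values under alternatives kept their direction and 0 passed the threshold. With 1 array left out, 54 of the 78 moved by over 1.5 times or turned. Fits of only the genotypes compared do not apply to the midpoint or to all 3 genotypes. An array left alone in its genotype is assumed to vary like the others. Values below are limma adjusted p values unless a log2 difference is named, and the cause of a change was not tested unless stated.

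With an estimated correlation 0 lists were called under any alternative, the lowest value being an adjusted p = 0.13. Leukocyte markers kept their call and direction under each alternative except the set tests. For Foxd1-/- against Foxd1+/+, lists gave an adjusted p = 0.70 with an estimated correlation (cell cycle, interferon, mesenchymal, posterior Hox) and an adjusted p = 0.49 (leukocyte), and fry's directional test gave 0.99 and 0.67. Against Foxd1+/- the called lists gave an adjusted p = 0.76 with an estimated correlation, or 0.43 for leukocytes, and fry gave 0.88 and 0.34. Cartilage in Foxd1+/- against Foxd1+/+ gave an adjusted p = 0.98 with an estimated correlation, and fry gave 0.985, with pluripotency turned in direction at 0.988.

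The replicate block, with the numbers pairing the arrays, changed 3 of these list calls: cartilage in Foxd1+/- against Foxd1+/+ (0.052), and pluripotency in Foxd1-/- against Foxd1+/- (0.035) and against Foxd1+/+ (0.014). Beyond these it changed the BMP and Wnt calls of both Foxd1-/- comparisons and the cartilage call at the midpoint, and no other call of the 3 genotype pairs or the midpoint. Quantile normalization ended cartilage (0.12), and in Foxd1-/- against Foxd1+/- cholesterol (0.13) and erythroid (0.051). Without the lowest 25% of genes these were 0.27, 0.064 and 0.078, and pluripotency in Foxd1+/- against Foxd1+/+ turned (0.999). Without the lowest 50%, cartilage was 0.54, cholesterol 0.11 and posterior Hox 0.36. Epithelial and pluripotency lists in Foxd1+/- against Foxd1+/+ turned (0.95 each), and pluripotency passed in Foxd1-/- against Foxd1+/- (0.036) and Foxd1+/+ (0.038). Posterior Hox was 0.055 with an offset of 16 and 0.099 without genes near Foxd1. In Foxd1-/- against Foxd1+/-, oxidative phosphorylation passed with quantile normalization (0.038) and neural crest passed without the lowest 50% (0.025).

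Without the arrays numbered 2 of Foxd1+/+ and Foxd1+/-, the Foxd1+/- against Foxd1+/+ values were 0.83 for cartilage, 0.0030 for epithelial (turned), 0.0030 for mesenchymal and 1.8e-05 for pluripotency, and Pou5f1 turned to a log2 difference of -0.81. In Foxd1-/- against Foxd1+/- they were 0.88 for cholesterol (turned), 0.062 for erythroid and 0.025 for pluripotency. In Foxd1-/- against Foxd1+/+ they were 3.1e-04 for epithelial and 2.6e-10 for pluripotency. The Xist term gave contractile 0.37, epithelial 0.0063 and pluripotency 0.0032 in Foxd1-/- against Foxd1+/-, and epithelial 0.0067, posterior Hox 0.12 and pluripotency 1.7e-04 against Foxd1+/+. Kdm5d turned to a log2 difference of 0.033, since the term takes up the Y-linked difference.

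Leaving out each array in turn leaves the replicate numbers unequal between genotypes. In Foxd1-/- against Foxd1+/+ the values ranged from 9.1e-25 to 0.46 for cell cycle, 3.1e-13 to 0.47 for interferon, 1.1e-14 to 0.51 for mesenchymal, 0.0077 to 0.46 for posterior Hox, 8.1e-11 to 0.46 for pluripotency and 4.8e-04 to 0.47 for epithelial genes. Against Foxd1+/- they ranged from 2.4e-23 to 0.89 for cell cycle, 9.7e-17 to 0.99 for interferon, 3.0e-06 to 0.68 for mesenchymal, 3.2e-06 to 0.84 for contractile, 0.017 to 0.19 for erythroid, 4.2e-04 to 0.86 for cholesterol, 6.2e-04 to 0.84 for pluripotency and 0.053 to 0.95 for epithelial genes. In Foxd1+/- against Foxd1+/+ they ranged from 0.0039 to 0.43 for cartilage, 9.6e-04 to 0.84 for epithelial, 1.3e-08 to 0.92 for mesenchymal and 1.1e-09 to 0.92 for pluripotency genes. The correlation of fold changes ranged from -0.21 to 0.74. Log2 differences ranged from -1.37 to 0.70 for Pou5f1 and -0.53 to 0.0079 for Sox2 in Foxd1-/- against Foxd1+/+, from -0.56 to 0.47 for Foxd1 and -0.88 to 1.18 for Pou5f1 in Foxd1+/- against Foxd1+/+, and from -0.017 to 1.24 for Oas2 in Foxd1-/- against Foxd1+/-.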

Other observations

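The tests in this part were chosen after the Foxd1 levels were seen. Since the order of Foxd1+/+ and Foxd1+/- is in doubt, the arrays labelled Foxd1-/- were set against the other 4 as 1 group, which does not depend on it. Both Foxd1-/- arrays were high in Xist and 2 of the other 4 were low, so this comparison partly follows the sex markers. limma called 0 genes, with 786 at an unadjusted p under 0.05 (1757 without Foxd1-/- replicate 1 and 391 without Foxd1-/- replicate 2), and 0 genes with the replicate block, with 2333 at that level and a smallest adjusted p of 0.078, where chance gives 997. Cell cycle genes were lower on the Foxd1-/- arrays in 40 of 40 members (median -0.25), leukocyte markers in 24 of 26 (-0.24) and contractile genes in 16 of 19 (-0.11). Interferon genes were higher in 33 of 33 members (0.82), mesenchymal genes in 32 of 41 (0.20) and cholesterol synthesis genes in 16 of 18 (0.06). limma's camera called these 6 lists, with adjusted p values of 2.8e-10, 1.8e-09, 0.0069, 9.9e-09, 1.1e-05 and 0.022. With an estimated correlation none was called in limma, the lowest being an adjusted p = 0.16 for the leukocyte list and an adjusted p = 0.75 for the others. With the replicate block camera called 9 lists, adding the pluripotency (limma adjusted p = 0.011, and adjusted p = 0.70 with an estimated correlation), BMP and Wnt (0.0091, and adjusted p = 0.35 with an estimated correlation) and inflammatory lists (0.0496, and adjusted p = 0.39 with an estimated correlation). Of the calls without the block, all but the leukocyte call were lost or turned with some array left out. Such an omission leaves the replicate numbers unequal. Within each number the Foxd1-/- array had the lowest cell cycle mean relative to the 6 arrays (0.13 against 0.24 and 0.19, and -0.46 against -0.09 and -0.005). It also had the highest interferon and mesenchymal means. In replicate 1 it was not at the end of the order for the contractile and cholesterol lists. Without Foxd1-/- replicate 2 the cell cycle direction turned (limma adjusted p = 0.60) and the interferon, mesenchymal, contractile and cholesterol lists did not pass (0.90, 0.60, 0.22 and 0.39). The contractile list also did not pass without Foxd1+/- replicate 1 (0.13) or Foxd1-/- replicate 1 (0.052), nor the cholesterol list without Foxd1+/+ replicate 1 (0.072) or Foxd1+/- replicate 2 (0.26). Adjusted over the list alone, 28 interferon, 18 mesenchymal, 17 cell cycle and 9 leukocyte genes passed with the replicate block, against 0, 0, 0 and 2 without it.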
